A study of Mus musculus with 5 samples.

How the data were processed

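The data are 5 libraries of mouse hindlimb muscle cells, 1 for each of the quiescent state and days 1, 2, 4 and 14 after notexin injury. Per the labels, the mice were C57BL/6J with a Hic1-driven CreERT2 recombinase and a tdTomato reporter, treated at 8 weeks of age with 2.5 mg of tamoxifen in 100 uL a day for 5 days, and left for 10 days of washout. Per the labels' protocols, tdTomato-positive mesenchymal progenitors were purified by flow cytometry and captured with the 10x Chromium 3' v2 chemistry. The authors deposited UMI counts per gene and barcode for each library, and the values were whole numbers that summed to a different total in each. Cell Ranger and the mm10 build are named, per the submitters' processing notes, and the version and the rule for calling cells are not given in the sources used here. The gene list holds 28001 features, tdTomato and CreERT2 included, of which 27645 had a gene record in GENCODE M21 on GRCm38 and 356 had none.

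Barcodes were kept with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. This kept 17085 of 17213 barcodes. Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells, called 15 doublets (0.0878%) by its automatic threshold, too few for the caller to have worked. The 15 were removed, leaving 17070 cells, and an alternative removed the 507 cells of highest score that the expected rates give. Doublets therefore remain in the values reported.

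Counts of the 5 libraries were scaled to 10000 per cell, log transformed and reduced to 2000 variable genes and 30 principal components, and clustered with 15 nearest neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). No batch integration was applied, since library and time point are the same, so a cluster mostly of 1 library may be that library. Of 15 marker lists, a list named a cluster when at least 50% of its genes, and at least 3, were at least 2-fold over the other cells and in at least 20% of the cluster's cells. Progenitor genes are in nearly all sorted cells, so a cluster was named progenitor-like when these genes were in a mean of at least 60% of its cells. A cluster whose 10 leading genes held more markers of another class stayed unnamed. The markers were fixed in advance and these naming limits were set after the data were examined. Of the 23 clusters, clusters 7, 19 and 21 stayed unnamed, the first 2 for leading genes with more tenocyte or Schwann cell markers than progenitor markers and the last for markers of both Schwann and perineurial cells. The quiescent library was also clustered alone at resolution 0.5.

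Raw counts were summed over progenitor-like cells of each library, 1735 cells with 6775676 UMIs for quiescent, 4395 with 41943766 at day 1, 2266 with 30801777 at day 2, 3645 with 29602753 at day 4 and 2070 with 10818625 at day 14. They were scaled to CPM, so that 3 counts, used as the floor for a gene at 0, are worth most in the quiescent library. Each day was compared with quiescent, and each library with the one before it. A gene was counted as higher or lower when the ratio was at least 2 and the higher library had at least 20 CPM. Ratios have exact conditional binomial 95% intervals, CPM values Poisson intervals and shares Clopper-Pearson intervals. Log2 ratios carry a prior of 1 CPM in each library. With 1 library per group no test was made, and DESeq2 1.42.0 and edgeR 4.0.16 (R 4.3.3) served only for alternative scaling factors.

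Genes named were the 12 of highest and 12 of lowest log2 ratio for each day against quiescent, and the 6 of each for consecutive libraries, among genes with at least 100 CPM in the higher library. Mitochondrially encoded, ribosomal protein, haemoglobin and predicted genes and markers of classes other than progenitor, tenocyte and mural were left out of that ranking, and 1 gene that the rule names is not reported here. Hic1, Pdgfra, Ly6a, Cd34 and tdTomato, and CreERT2 in the counts, are always given. From each list at most 4 members of largest absolute log2 ratio with at least 20 CPM were named. The 28 gene lists cover chemokines and cytokines, early response and dissociation stress, S phase, G2/M phase, interstitial matrix, basement membrane, contractile and myofibroblast genes, TGF-beta, growth factors, quiescence and cell cycle exit, resident progenitor genes, complement, matrix proteases, adipogenic, chondro-osteogenic, tenogenic and mural genes, glycolysis, oxidative phosphorylation, unfolded protein response, collagen processing, interferon response, ribosome biogenesis, hypoxia, Wnt signalling, Hedgehog and Notch signalling, hyaluronan and proteoglycan, and antigen presentation. Some genes are in more than 1 list, such as Tnc, which is an interstitial matrix and a tenogenic gene. A list's median log2 ratio over members with at least 5 CPM was set against 10000 random lists of the same size matched on mean expression in 20 bins, and stood apart at or beyond percentiles 2.5 and 97.5, as a description of these libraries.

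Depth differs between libraries, so shares of cells with transcripts of a gene or list were read after each cell was thinned to 2500 UMIs, the largest multiple of 500 that at least 80% of progenitor-like cells of every library reached. The comparisons, filters, gene lists, markers, rule for named genes and first alternatives were chosen before the data were examined. These alternatives were a filter of 1000 genes and 5% mitochondrial UMIs, doublets kept, resolution 2.0, TMM and DESeq2 scaling, the mean over cells, all classes, minimums of 5 and 50 CPM, list members with at least 20 CPM, at least 3 UMIs of a list and no thinning. Alternatives added after seeing the data were removal of the highest doublet scores, addition of unnamed clusters with progenitor markers, only cells with at least 3647 UMIs, and removal of the 33 genes lower in the day 2 and day 4 libraries in 3 cell classes.

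The ratio and list steps were tested on simulated data drawn as Poisson counts from the quiescent means and the real library sizes, with 200 genes changed. Of 100 genes changed 4-fold, 100 were counted for day 1, 99 for day 2, 99 for day 4 and 100 for day 14, and 100 of 100 changed 8-fold were counted for each. Of unchanged genes, 0 of 5333, 5355, 5333 and 5368 were counted in the same order. The simulated libraries differ by counting error only, so this does not show how many genes animals or preparation would move 2-fold. The 95% intervals held the true ratio in 95.2%, 95.0%, 94.8% and 94.9% of 5533, 5554, 5532 and 5568 genes, and 6.25%, 4.75%, 4.00% and 4.75% of 400 random lists stood apart. Near-identical transcript ends were searched with blastn 2.17.0 over the last 400 bases, at 95% identity over at least 90 bases. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.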

Results

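Mesenchymal progenitors of mouse hindlimb muscle were profiled before injury and at days 1, 2, 4 and 14 after notexin, a phospholipase from snake venom that destroys muscle fibres. The cells were sorted for tdTomato, a red fluorescent protein switched on in cells that had expressed Hic1, a transcriptional repressor, and in their descendants. Each of the 5 groups was 1 library of single-cell 3' transcripts, so the differences below have no replicate check and no p-value, and each compares libraries. The quiescent library held 2170 barcodes with 8043771 unique molecular identifiers (UMIs), day 1 held 4820 with 44552329, day 2 held 2556 with 32843041, day 4 held 4140 with 32283940 and day 14 held 3527 with 17612150. Median depth per barcode ran from 3736 UMIs in the quiescent library to 10739 at day 2. The lowest number of UMIs of any barcode was 797 in the quiescent library, 2334 at day 1, 3647 at day 2, 2311 at day 4 and 1335 at day 14, so that cells poor in RNA could enter some libraries and not others. Values in parentheses after a fold or a share are 95% intervals, which cover counting error only.

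Progenitor-like cells, named from fibroblast genes such as Pdgfra, Dcn and Col1a1, made up most of every library. Their share was 81.4% (79.7 to 83.0) in the quiescent library, 91.3% at day 1, 89.0% at day 2, 88.8% at day 4 and 59.6% at day 14. Tenocyte-like cells, which carried the tendon genes Tnmd, Fmod and Kera, were 5.11% of quiescent cells, 4.26% at day 1, 2.51% at day 2, 2.51% at day 4 and 21.7% at day 14. Mural-like cells, with the pericyte genes Rgs5, Kcnj8 and Abcc9, were 5.35%, 1.95%, 1.34%, 2.44% and 7.09% in the same order. The rest was 18 myogenic cells and 3 unnamed clusters, which held 8.02%, 2.51%, 7.19%, 6.02% and 11.4% of the cells in that order. Mural-like cells had a median of 1432 UMIs in the quiescent library, against 3941 in progenitor-like cells. Among cells with at least 3647 UMIs, the limit of the day 2 library, the mural share was 0.444% in the quiescent library and 2.78% at day 14, and the tenocyte share 4.62% (3.47 to 6.01) and 22.7% (21.05 to 24.5). The lower limits could thus set the mural share, while the tenocyte share at day 14 was above the quiescent one with the limit as well. The sort could set any of the shares.

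**Figure D1:**
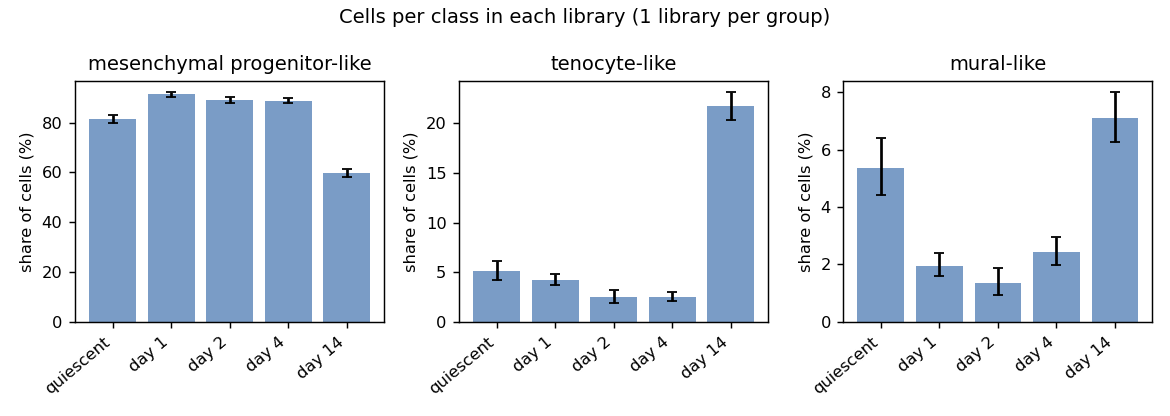
Share of cells (%, bars) in the progenitor-like, tenocyte-like and mural-like classes of each library, with 95% Clopper-Pearson intervals (lines) that cover counting error only. Tenocyte-like cells were 21.7% of the day 14 library and 5.11% of the quiescent library.

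Clustered on its own, the quiescent library held 4 progenitor-like populations, each led by different genes. The largest, 35.4% of cells, was led by Hsd11b1, which regenerates active glucocorticoid, with Cxcl14 and Smoc2. A population of 23.1% was led by Stmn4, Efemp1 and Cd55, one of 17.2% by Clu, Gdf10 and Prg4, and one of 12.3% by Dmkn, Sbsn and Krtdap. Mural-like cells were 5.49% and tenocyte-like cells 5.11% there, and an unnamed cluster with perineurial genes was 1.41%.

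The day 1 comparison asked what the progenitors expressed soon after injury. Chemokines that draw neutrophils and monocytes were far higher than in the quiescent library. Cxcl5 was at 2889 CPM (counts scaled to the summed UMIs of the class in each library) against 0, at least 6524-fold higher by a floor of 3 counts in the quiescent library. Ccl2 was 28.6-fold (26.9 to 30.4) higher at 4315 against 151 CPM, Ccl7 18.6-fold (17.5 to 19.9) higher at 2545 against 136 CPM and Cxcl2 30.03-fold (23.7 to 38.7) higher. Timp1, an inhibitor of matrix proteases, was 120-fold (106 to 136) higher at 4727 against 39.4 CPM. Matrix and progenitor genes were lower, among them the basement membrane collagen gene Col15a1 at 18.7-fold (17.2 to 20.3) and Itih5, whose product binds hyaluronan, at 14.5-fold (13.8 to 15.3).

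Other genes with the highest ratios at day 1 were Saa3, an acute-phase gene (at least 407-fold higher), Il1rl1, the receptor of interleukin 33 (178-fold, 76.2 to 548), the protease gene Mmp3 (29.2-fold, 25.4 to 33.8), Steap1 (29.3-fold, 19.8 to 45.3), Cthrc1 (28.9-fold, 19.6 to 44.8), Angptl4, an inhibitor of lipoprotein lipase (20.3-fold, 17.1 to 24.3) and the asparagine synthetase gene Asns (13.1-fold, 10.3 to 16.9). The lowest ratios were those of Stmn4 (43.2-fold lower, 36.2 to 51.8), Pthlh (27.8-fold, 24.3 to 32.0), Hmcn2 (27.7-fold, 23.9 to 32.2), Abca8b (22.1-fold, 19.3 to 25.5), Angptl1 (20.1-fold, 18.7 to 21.7), Inmt (19.4-fold, 17.6 to 21.4), Cilp (18.2-fold, 16.5 to 20.2), Pamr1 (17.0-fold, 14.8 to 19.7), G0s2, an inhibitor of lipolysis (15.9-fold, 14.6 to 17.2) and the elastic fibre gene Mfap4 (15.6-fold, 13.9 to 17.4).

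All 16 ribosome biogenesis genes were at least 2-fold higher at day 1, with a median log2 ratio of 2.31. They included Nhp2 at 8.61-fold (7.82 to 9.50) and the rRNA methyltransferase gene Fbl at 6.50-fold (5.99 to 7.07). Of 20 S phase genes, 18 were higher (median 2.31), among them the replication helicase genes Mcm5 at 31.9-fold (18.6 to 59.9) and Mcm2 at 18.6-fold (12.1 to 30.1). Of 20 G2/M genes, only 4 reached 5 CPM in either library, with a median of -1.47 inside the range of random lists, a sign that turned with TMM or DESeq2 factors, which also altered which 4 genes reached that level. Glycolysis genes had a median of 1.37, with Ldha, lactate dehydrogenase, 5.74-fold (5.47 to 6.02) higher. The chemokine list had 10 of 17 members higher (median 1.14), and the contractile list 8 of 15 (median 1.07), including Tagln at 16.8-fold (10.6 to 28.4) and the smooth muscle actin gene Acta2 at 7.80-fold (5.63 to 11.1). The chondro-osteogenic list also lay above its random lists (median 0.56, 2 of 7 members higher and 2 lower), a position held under 4 of 11 alternatives. The contractile position held under 10 of 11.

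All 13 basement membrane genes were at least 2-fold lower at day 1 (median -2.20), with Nid2 at 10.8-fold (9.39 to 12.5) and the laminin gene Lama2 at 6.64-fold (6.20 to 7.11). Of 23 interstitial matrix genes, 16 were lower and 3 higher (median -1.76). Eln, the elastin gene, was 9.79-fold (9.05 to 10.6) lower and Tnc, tenascin C, 55.8-fold (31.9 to 108) higher. Genes tied to quiescence and cell cycle exit were lower in 14 of 16 cases (median -1.91), with Cdkn1c, a cyclin-dependent kinase inhibitor, 24.7-fold (19.6 to 31.5) lower and Txnip 8.06-fold (7.54 to 8.61) lower. Of 19 resident progenitor genes, 15 were lower (median -1.80), among them Clec3b at 13.2-fold (12.9 to 13.5), Tek at 12.2-fold (10.6 to 13.9) and Dpp4 at 9.49-fold (8.69 to 10.4). Wnt signalling genes had a median of -1.78, led by Sfrp2, a secreted Wnt binder, 14.1-fold (11.5 to 17.5) lower. Medians were -1.61 for the 4 mural genes compared, -0.98 for complement, -0.95 for early response genes, -0.93 for growth factors and -0.92 for collagen processing, each below its random lists. The growth factor and complement positions each held under 9 of 11 alternatives. Bmp4 was 7.40-fold (6.66 to 8.22) lower, Cd55 7.77-fold (7.33 to 8.23) lower and Jund 6.88-fold (6.40 to 7.41) lower at day 1.

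In total 937 genes were at least 2-fold higher and 1480 lower at day 1, of 6052 with at least 20 CPM in the higher library. The split depended on scaling. TMM factors gave 1946 higher and 726 lower, and DESeq2 size factors 1977 and 708, with the median of all genes shifted by 0.53 and 0.55 on the log2 scale. Under each scaling, whose random lists shift with it, the chemokine, S phase and ribosome biogenesis medians stood above and the basement membrane median below their random lists. Most progenitor-like cells lay in clusters 1, 2, 6 and 11 of the joint clustering in the quiescent library and in clusters 3, 8, 9 and 10 at day 1.

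**Figure D2:**
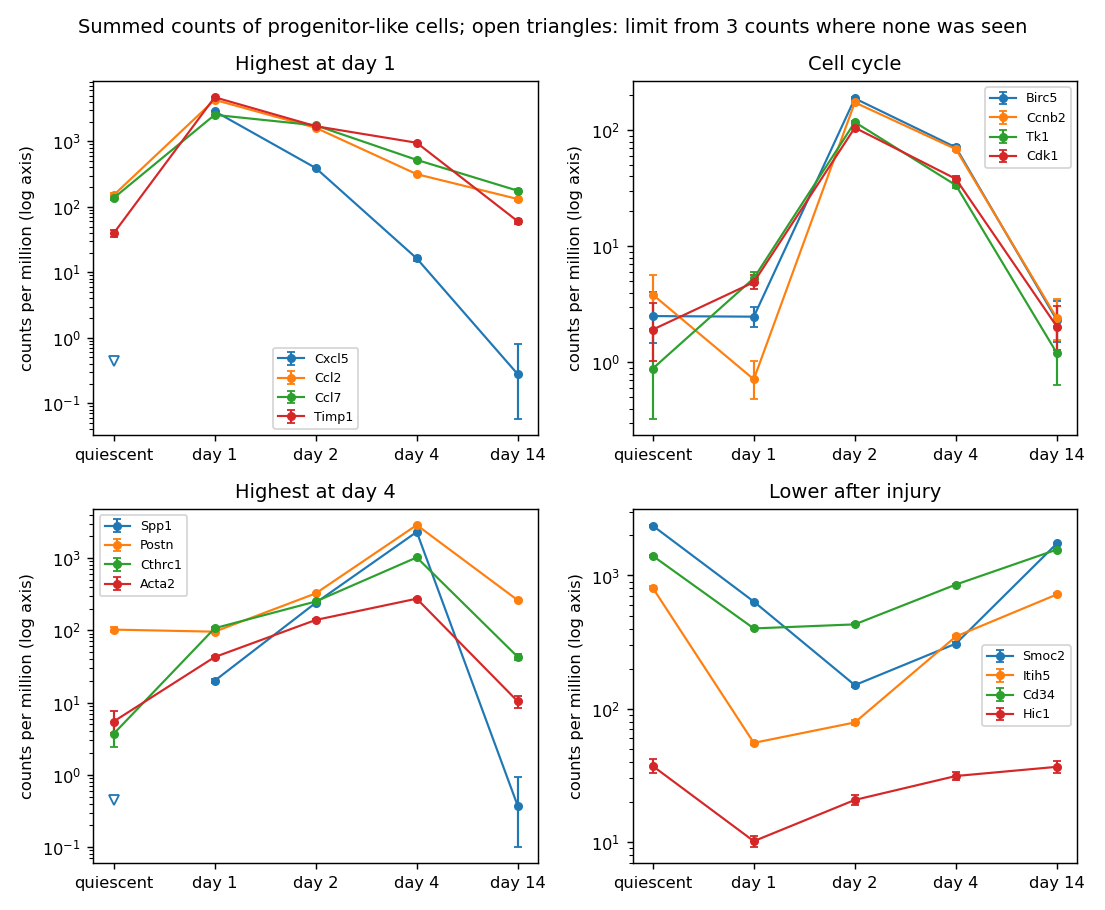
Summed counts as CPM (log axis) of 16 genes in progenitor-like cells of the 5 libraries, with 95% Poisson intervals (lines); open triangles mark the limit from 3 counts where no count was seen. Cxcl5 was at 2889 CPM at day 1, Birc5 at 188 at day 2 and Spp1 at 2298 at day 4.

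Day 2 was compared with the quiescent library in the same way. Genes of DNA replication and mitosis were higher, and Cxcl5 and Spp1 had the highest ratios. Birc5, the survivin gene, was 75.0-fold (46.8 to 129) higher at 188 against 2.51 CPM, Tk1, thymidine kinase, 133-fold (60.9 to 362) higher and Rrm2, a ribonucleotide reductase subunit, 62.4-fold (37.1 to 114) higher. Cxcl5 was at 392.4 CPM, at least 886-fold above the quiescent floor, and Spp1, the osteopontin gene, was at 239.6 CPM, at least 541-fold higher. Smoc2, which encodes a matrix calcium-binding protein, was 15.7-fold (15.2 to 16.2) lower at 150.5 against 2362 CPM.

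All 20 G2/M genes were at least 2-fold higher at day 2 (median 4.14), including the mitotic kinase gene Cdk1 at 54.9-fold (32.0 to 103) and the cyclin gene Ccnb2 at 45.3-fold (30.9 to 69.4). Of 19 S phase genes, 18 were higher (median 2.85). The highest ratios also took in Spc24 (104-fold, 50.3 to 258), Cdca3 (48.7-fold, 30.4 to 83.7), Cthrc1 (67.8-fold, 45.9 to 105), Timp1 (43.4-fold, 38.4 to 49.1) and Stmn1, a microtubule destabilizer (28.8-fold, 23.0 to 36.4). Hmmr, the hyaluronan-mediated motility receptor, was 103-fold (40.2 to 379) higher, in a hyaluronan list with 4 of 14 members higher and a median of -0.09, a sign that turned with TMM or DESeq2 factors. Chemokines had a median of 2.16, with Ccl7 12.9-fold (12.1 to 13.8) and Il6, interleukin 6, 10.9-fold (9.58 to 12.6) higher. Glycolysis genes had a median of 1.35, contractile genes 1.18 with Acta2 25.4-fold (18.4 to 36.2) higher, and chondro-osteogenic genes 1.05 with Runx1 5.21-fold (3.89 to 7.14) higher. The ribosome biogenesis median was 0.98, 8 of 16 members being higher. The chondro-osteogenic position held under 8 of 11 alternatives.

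The lowest ratios at day 2 were those of Hmcn2 (36.0-fold lower, 29.8 to 43.7), Vwa1 (18.1-fold, 15.5 to 21.1), Fbln7 (16.9-fold, 14.6 to 19.7), Pthlh (13.1-fold, 11.7 to 14.7), Efhd1 (12.9-fold, 11.7 to 14.2), Jund (11.6-fold, 10.6 to 12.8), Ltbp4, a latent TGF-beta binding protein (11.2-fold, 10.4 to 11.96), Stmn4 (10.4-fold, 9.27 to 11.7), Itih5 (10.2-fold, 9.74 to 10.7), Ier2 (9.91-fold, 9.38 to 10.5) and the heat shock gene Hspa1b (9.18-fold, 8.32 to 10.1). Of 13 basement membrane genes, 13 were lower (median -1.77), with Nid1 at 4.29-fold (4.14 to 4.44). Resident progenitor genes were lower in 12 of 19 cases (median -1.72), with Gsn, gelsolin, at 6406 against 35170 CPM. Medians were -1.12 for quiescence genes, -1.09 for early response genes, -1.02 for TGF-beta genes, -0.95 for Wnt genes, -0.92 for complement, -0.85 for matrix proteases and -0.83 for interstitial matrix. The complement position held under 10 of 11 alternatives and the Wnt position under 7. Within these lists Tgfbi was 5.15-fold (4.81 to 5.51) lower, Timp3 7.87-fold (7.47 to 8.29) lower, Dcn, decorin, 3.67-fold (3.65 to 3.70) lower and the crosslinking enzyme gene Lox 9.11-fold (7.58 to 11.1) higher.

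Of 6082 genes, 703 were at least 2-fold higher and 1081 lower at day 2, against 1152 and 695 with TMM and 1284 and 635 with DESeq2 factors, whose medians lay 0.23 and 0.28 higher on the log2 scale. Most of the day 2 cells were in clusters 4, 12 and 15. In progenitor-like cells 74 genes were more than 2-fold lower, after 5 CPM was added to each level, in both the day 2 and day 4 libraries than in each of the other 3, among them Smoc2, Apoe, Cyc1 and Junb, and 33 of the 74 were also lower in tenocyte-like and mural-like cells, among them Ier2, Nol7, Emc6, Tomm20 and Cox5a. These 2 libraries and the other 3 are called library sets here, and for these genes set and time point cannot be told apart in day 2 or day 4 against the quiescent library, day 2 against day 1 or day 14 against day 4.

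The share of progenitor-like cells with at least 2 UMIs of G2/M genes, after each cell was thinned to 2500 UMIs, was 28.3% (26.4 to 30.2) at day 2 and 8.33% (7.44 to 9.28) at day 4. It was 0.354% in the quiescent library, 0.577% at day 1 and 0.230% at day 14. For S phase genes it was 10.1% in the quiescent library, 40.8% at day 1, 34.9% at day 2, 15.9% at day 4 and 10.6% at day 14, and with at least 3 UMIs 1.56% in the quiescent library, 25.6% at day 1, 24.4% at day 2, 6.29% at day 4 and 1.95% at day 14. Without thinning, G2/M shares were 0.634%, 4.51%, 48.5%, 13.6% and 0.531% and S phase shares 20.7%, 77.1%, 71.4%, 52.8% and 31.5%. Thinning left out 324, 59, 0, 54 and 328 shallower cells in the same order. Free RNA could add to such shares and was not removed.

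**Figure D3:**
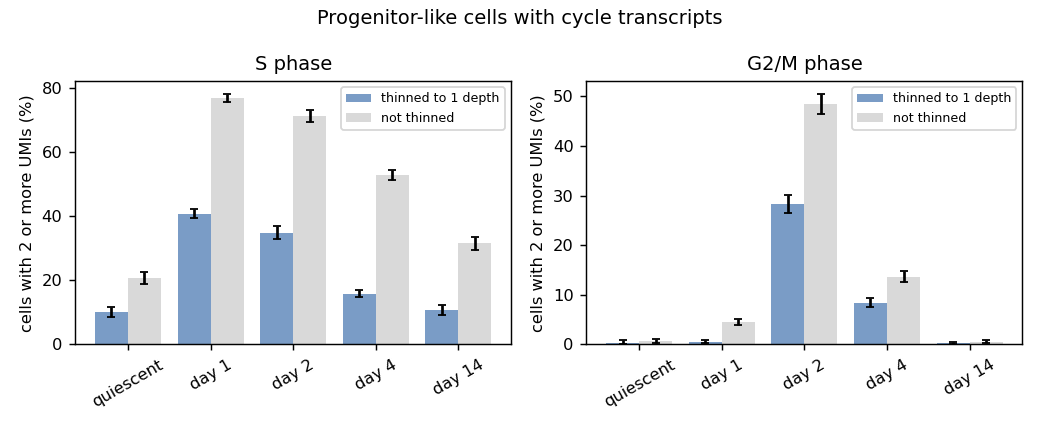
Share (%) of progenitor-like cells with at least 2 UMIs of the S phase or G2/M genes in each library, after thinning to 2500 UMIs per cell (blue) and without thinning (grey), with 95% Clopper-Pearson intervals. G2/M shares after thinning were 28.3% at day 2 and 8.33% at day 4, and under 1% in the other libraries.

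Single genes were read in thinned cells in the same way, beside mural-like cells as a class that should hold few of their transcripts. Few mural-like cells were deep enough to thin, so their shares are loose. There were 12 in the quiescent library, 81 at day 1, 34 at day 2, 92 at day 4 and 137 at day 14. Cxcl5 was found in 0 of 1411 quiescent cells, 55.5% of cells at day 1, 18.0% at day 2, 1.53% at day 4 and 0 of 1742 at day 14. Its share in mural-like cells was 12.3% at day 1 (10 of 81 cells) and 2.94% at day 2 (1 of 34). Without thinning the progenitor-like shares were 67.7% and 33.4%. Ccl2 was in 4.82%, 71.5%, 46.7%, 12.9% and 4.94% of progenitor-like cells in time order, against 39.5% of mural-like cells at day 1. Unthinned, Ccl2 was in 79.3% at day 1. Cd34, a surface marker of these progenitors, was in 93.5%, 53.0%, 58.5%, 71.0% and 92.0%, against at most 23.5% of mural-like cells, and unthinned in 93.2%, 78.1%, 89.0%, 87.4% and 93.0%. Postn was in 74.1% of progenitor-like cells at day 4 (82.0% unthinned) and in 57.6% of mural-like cells. At day 2 its share was also higher in progenitor-like cells. It was higher in mural-like cells in the quiescent library, in 5 of 12 cells against 9.4%. The same held at day 1 (19.8% against 12.5%) and day 14 (30.7% against 19.3%). Mural-like cells thus do not lack Postn and cannot show what free RNA adds to its share. The Acta2 share in progenitor-like cells was 0.921% in the quiescent library and 16.4% at day 4 (27.8% unthinned). In tenocyte-like cells it was 20.2% and 18.8%. That class does not lack Acta2 and cannot show what free RNA adds, so the share is not read as expression per cell. Before thinning, progenitor-like cells had median depths of 3941, 9035, 11671, 7271 and 5027 UMIs in time order, mural-like cells 1432, 2996, 4700, 3694 and 2714, and tenocyte-like cells 5562 at day 4.

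At day 4 the interferon and contractile lists lay above their random lists, and matrix genes such as Spp1, Postn and Tnc were among those of highest ratio. Spp1 was at 2298 against 0 CPM, at least 5190-fold higher. Postn, periostin, was 28.0-fold (26.0 to 30.2) higher at 2860 against 102 CPM, Cthrc1 276-fold (187 to 427) higher at 1020 against 3.69 CPM, Tnc 118-fold (67.7 to 229) higher and Acta2 50.1-fold (36.3 to 71.2) higher. Isg15, an interferon-induced ubiquitin-like protein, was 12.1-fold (10.4 to 14.1) higher, and Irf7, an interferon regulatory factor, 8.63-fold (7.44 to 10.1). Smoc2 was 7.66-fold (7.47 to 7.86) lower and Bmp4, a bone morphogenetic protein, 6.07-fold (5.44 to 6.77) lower.

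Hp, haptoglobin, had 1 count in the quiescent library and was 701-fold (126 to 27690) higher at day 4. Ctsc, the cathepsin C gene, was 87.3-fold (54.5 to 150) higher, H19, an imprinted noncoding RNA, 37.7-fold (30.1 to 47.9), Timp1 24.2-fold (21.4 to 27.4), Cxcl9 23.4-fold (16.4 to 34.5), Tmem176a 21.6-fold (17.6 to 26.9) and Tmem176b 14.9-fold (12.9 to 17.4). Of 16 interferon genes, 11 were higher (median 1.58), with Ifit3 at 5.83-fold (4.97 to 6.89) and Bst2 at 5.17-fold (4.84 to 5.53). Antigen presentation genes were higher in 6 of 9 cases (median 1.15), with the peptide transporter gene Tap1 at 3.60-fold (2.92 to 4.47) and B2m at 2.25-fold (2.21 to 2.30). The contractile list had 9 of 16 members higher (median 1.59), with Lrrc15 at 68.0-fold (29.1 to 209.8), and the chondro-osteogenic list 4 of 7 (median 1.70), with the osteoblast regulator Runx2 at 5.05-fold (3.65 to 7.19). G2/M genes were higher in 20 of 20 cases (median 2.82, or 2.89 with genes at 0 counts set to their bound) and S phase genes in 12 of 18 (median 1.45).

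Interstitial matrix genes had a median of 0.61 at day 4, with 8 of 23 higher, among them Col8a1 at 10.5-fold (9.58 to 11.6) and Lox at 12.2-fold (10.2 to 14.8). Medians were 0.74 for collagen processing, 0.82 for matrix proteases with Mmp13 at least 88.4-fold higher, 0.94 for chemokines with Ccl8 9.63-fold (8.28 to 11.3) higher, 0.69 for glycolysis and 0.60 for Wnt genes. Mmp13 was at 6555 CPM in tenocyte-like cells of the day 4 library. Free RNA from them or doublets could add to its value in progenitor-like cells, which was not tested. The tenogenic list (median 1.03, 3 of 5 higher) and the mural list (0.96, 2 of 5 higher) hold markers of the other sorted classes, and Tnc and Pdgfrb were among their members. With all cells in place of progenitor-like cells the tenogenic median was -1.87 and the mural median -0.57. Positions held under 10 of 11 alternatives for the interstitial and chondro-osteogenic lists, 9 for the mural list, 8 for the tenogenic list and 7 for Wnt genes. Wisp1, a matricellular signalling gene, was 70.3-fold (37.0 to 154) higher in a growth factor list whose median was -0.21. Early response genes (median -1.08), basement membrane genes (-0.85, 4 of 13 lower), resident progenitor genes (-0.76, 9 of 19 lower) and quiescence genes (-0.59, 5 of 16 lower) lay below their random lists.

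Other genes lowest at day 4 were Vwa1 (10.3-fold lower, 9.13 to 11.8), Ier2 (9.81-fold, 9.28 to 10.4), Lysmd2 (8.51-fold, 7.70 to 9.42), Inmt (8.49-fold, 7.83 to 9.21), Hmcn2 (8.00-fold, 7.20 to 8.90), Nol7 (7.80-fold, 6.99 to 8.71), Jund (6.82-fold, 6.29 to 7.40), Abca8b (6.49-fold, 5.87 to 7.18), Pcolce2, an enhancer of procollagen cleavage (6.28-fold, 5.98 to 6.59) and Plac9b (5.92-fold, 5.41 to 6.48), which has a near-identical paralog and is uncertain. Of 5962 genes, 394 were at least 2-fold higher and 612 lower, against 503 and 468 with TMM and 531 and 441 with DESeq2 factors, which shifted the median of all genes by 0.12 and 0.14. Clusters 0 and 1 held most of the day 4 cells.

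At day 14 the library lay close to the quiescent one, with 50 genes at least 2-fold higher and 52 lower of 5751. Mfap4, an elastic fibre gene, was 3.10-fold (2.90 to 3.31) higher, Mgp, an inhibitor of calcification, 3.04-fold (2.97 to 3.12) higher at 3393 against 1115 CPM and Postn 2.55-fold (2.35 to 2.78) higher. The immediate early genes Egr1 and Fosb were 2.30-fold (2.21 to 2.39) and 2.18-fold (2.01 to 2.37) lower. They belong to the early response and dissociation stress list, whose median lay below its random lists at every day. Handling of the quiescent library and time point cannot be told apart for it.

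The genes of highest ratio at day 14 also took in Apod (2.64-fold, 2.53 to 2.75), Mdk (2.62-fold, 2.31 to 2.97), Ifi30 (2.42-fold, 2.20 to 2.65), Apoe (2.40-fold, 2.22 to 2.60), Col8a1 (2.03-fold, 1.83 to 2.27), Fxyd6 (2.00-fold, 1.79 to 2.24), Ctsk (1.97-fold, 1.87 to 2.08), Grina (1.91-fold, 1.71 to 2.14) and Pdgfrl (1.91-fold, 1.74 to 2.10). Apoe was at 1896 CPM in tenocyte-like cells of the day 14 library and 276 in progenitor-like cells. Free RNA or doublets could add to the latter value, which was not tested. The lowest took in Atp5k (2.59-fold lower, 2.38 to 2.80), Btg2 (2.34-fold, 2.23 to 2.46), Dusp1 (2.30-fold, 2.17 to 2.44), Ddit4 (2.23-fold, 2.01 to 2.48), Klf9 (2.17-fold, 2.00 to 2.36), Ccnl1 (2.15-fold, 1.94 to 2.38), Tnfaip2 (2.05-fold, 1.86 to 2.27), Rhob (2.02-fold, 1.84 to 2.23) and Bhlhe40 (1.89-fold, 1.70 to 2.10). Early response genes had a median of -0.61, basement membrane genes -0.27, hyaluronan genes -0.26 and the 3 G2/M genes compared -1.05. Medians above the random lists were 1.83 for tenogenic genes, 0.57 for the 4 mural genes compared, 0.46 for complement, 0.34 for adipogenic genes, 0.16 for chemokines and 0.16 for interstitial matrix. The chemokine and interstitial positions held under 7 of 11 alternatives each, and the hyaluronan position under 10. Tnmd, a tendon membrane protein, was 3.74-fold (2.99 to 4.72) higher and Fmod, fibromodulin, 5.28-fold (4.02 to 7.03) higher in a library with 21.7% tenocyte-like cells, and Tnmd was in 7.52% of thinned progenitor-like cells and 8.03% of mural-like cells (13.8% and 7.72% unthinned), with median depths of 5027 and 2714 UMIs. Clusters 1, 2, 6 and 11 held most of the progenitor-like cells in both libraries.

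**Figure D4:**
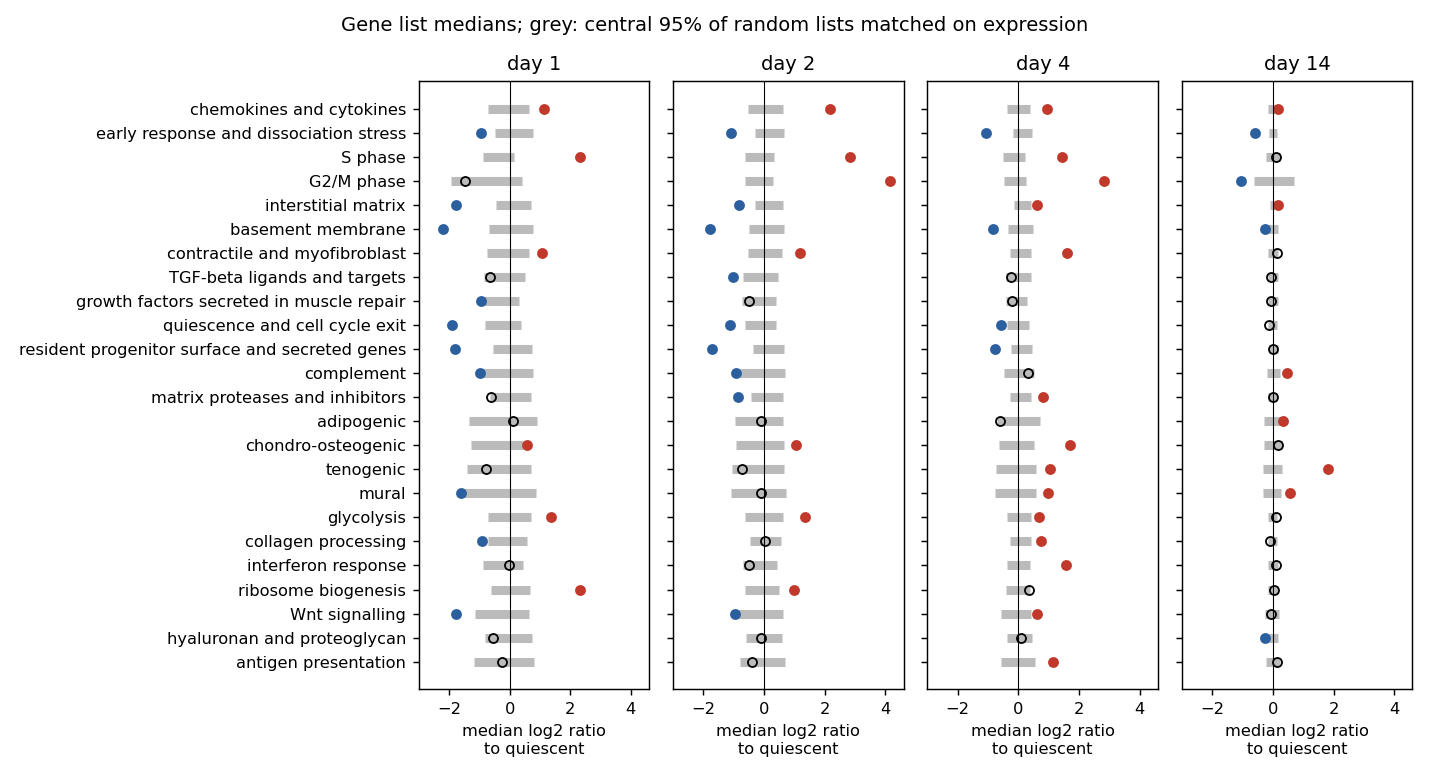
Median log2 ratio to the quiescent library (points) of 24 gene lists in progenitor-like cells at each day, with the central 95% of random lists matched on expression (grey bars); red points lie above, blue points below and open points inside those bars. The G2/M median was 4.14 at day 2 and 2.82 at day 4, and the basement membrane median was -2.20 at day 1.

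Lists that stayed inside their random range at every day against the quiescent library were oxidative phosphorylation (median 0.75 at day 1), the unfolded protein response (0.57), hypoxia (-0.74, or 0.06 over the 8 of 9 members that reached 5 CPM with DESeq2 factors) and Hedgehog and Notch signalling (-1.13). In them Cox5a, a respiratory chain subunit, was 2.78-fold (2.61 to 2.97) higher at day 1, Mif 12.02-fold (11.2 to 12.9) higher and Hes1, a Notch target, 9.41-fold (8.19 to 10.8) lower.

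Hic1 itself was at 37.2 CPM in the quiescent library, 10.2 at day 1, 20.7 at day 2, 31.3 at day 4 and 36.7 at day 14. It was 3.66-fold (3.12 to 4.29) lower at day 1, and its day 14 level was within counting error of the quiescent one (1.01-fold lower, 0.862 to 1.19). Cd34 was 3.50-fold (3.41 to 3.59) lower at day 1 and 1.64-fold (1.60 to 1.68) lower at day 4. Pdgfra, a growth factor receptor, was 1.31-fold (1.25 to 1.38) lower at day 1, with a log2 ratio of -0.39 that became 0.15 with TMM and 0.17 with DESeq2 factors, and 1.66-fold (1.58 to 1.75) lower at day 4. Ly6a, the Sca-1 surface protein, was 1.34-fold (1.32 to 1.37) higher at day 2. Its share of thinned progenitor-like cells was 92.9% in the quiescent library, 86.9% at day 1, 97.4% at day 2, 92.3% at day 4 and 88.9% at day 14. The tdTomato transcript ran from 742 CPM at day 2 to 1649 at day 14. CreERT2 had at most 3 counts in any library.

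Consecutive libraries were compared to follow the order of the time course. From day 1 to day 2 mitotic genes were higher and the interleukin 33 receptor gene was lower. Ccnb2 was 243-fold (169.9 to 360.4) higher at 174 against 0.715 CPM, Cdca3 171-fold (119.5 to 254), Birc5 75.9-fold (62.5 to 93.0), the centromeric histone gene Cenpa 69.9-fold (55.0 to 90.3), Cdc20 31.8-fold (27.1 to 37.4) and Spc24 26.9-fold (23.0 to 31.6). Il1rl1 was 26.6-fold (22.7 to 31.5) lower, Apoe 15.3-fold (13.9 to 16.9), the retinaldehyde dehydrogenase gene Aldh1a3 11.1-fold (10.4 to 11.9), Emc6 9.10-fold (8.25 to 10.1), Tomm20 8.20-fold (7.62 to 8.83) and Cyc1 8.02-fold (7.51 to 8.56). Apoe, Emc6, Tomm20 and Cyc1 are among the 74 genes that part the library sets. Of 18 chemokine genes, 5 were lower and 2 higher (median -0.55). The ribosome biogenesis median was -1.21, 14 of 16 members being lower, and the interstitial matrix median 1.05. In total 530 genes were higher and 436 lower, against 331 and 801 with TMM and 357 and 755 with DESeq2 factors.

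From day 2 to day 4, libraries of the same set, interferon and interstitial matrix genes were higher, and Cxcl5 and 3 genes of sterol synthesis were among the lowest ratios. Cxcl9 was 44.6-fold (35.4 to 56.9) higher, Mfap4 30.7-fold (28.3 to 33.4), Cilp 20.04-fold (19.0 to 21.2), Pdgfrl 14.1-fold (13.1 to 15.2), Ifit3 12.9-fold (11.5 to 14.5) and Isg15 12.1-fold (11.2 to 13.0). Idi1, Fdps and Sqle, enzymes of the mevalonate and sterol pathway, were 9.94-fold (9.09 to 10.9), 7.74-fold (7.40 to 8.10) and 7.43-fold (6.82 to 8.12) lower, Cxcl5 24.1-fold (22.0 to 26.4), Cxcl2 9.10-fold (8.22 to 10.1) and S100a4 7.20-fold (6.99 to 7.41). Of 16 interferon genes, 13 were higher (median 1.97), and of 23 interstitial matrix genes, 18 (median 1.26), while S phase genes were lower in 18 of 19 cases (median -1.51). Oxidative phosphorylation (-0.35) and the unfolded protein response (-0.42) lay below their random lists here, and Hedgehog and Notch signalling (0.84, 4 of 8 higher) above. In total 391 genes were higher and 214 lower, against 333 and 285 with TMM and 319 and 311 with DESeq2 factors.

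From day 4 to day 14 the interferon list was lower in 11 of 16 members (median -1.40) and the contractile list in 9 of 16, while of 23 interstitial matrix genes 7 were lower and 15 within 2-fold (median -0.48). Spp1 was 6215-fold (2427 to 22810) lower with 4 counts at day 14, Hp 159.9-fold (77.5 to 398), Ctsc 65.8-fold (47.5 to 94.1), Tnc 50.4-fold (37.6 to 69.2), Cxcl9 30.5-fold (22.2 to 43.1) and Acta2 26.4-fold (21.9 to 32.1). Apoe was 10.9-fold (10.1 to 11.9) higher, Vwa1 10.2-fold (9.05 to 11.5), Inmt 8.71-fold (8.08 to 9.39), Ier2 7.80-fold (7.39 to 8.23), Lysmd2 7.61-fold (6.92 to 8.38) and Pcolce2 7.08-fold (6.78 to 7.40). Apoe and Ier2 part the library sets. Free RNA from tenocyte-like cells, with Apoe at 1896 CPM at day 14, could also add to its ratio, which was not tested. The contractile median was -1.58 and the G2/M median -3.30, all 20 G2/M genes being lower. In total 493 genes were higher and 345 lower, against 393 and 408 with TMM and 364 and 434 with DESeq2 factors. Between these pairs TMM shifted the median of all genes by -0.30, -0.11 and -0.09 in time order, and DESeq2 factors by -0.27, -0.14 and -0.13.

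Across 6509 genes, which are not independent replicates, Pearson correlations of log2(CPM + 1) with the quiescent library were 0.765 at day 1, 0.797 at day 2, 0.859 at day 4 and 0.979 at day 14. Of 1260 genes with at least a 4-fold range, 298 were highest in the quiescent library, 285 at day 1, 152 at day 2, 234 at day 4 and 291 at day 14, against 158, 638, 163, 185 and 178 with TMM. In GRCm38 with GENCODE M21, Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), Birc5 (ENSMUSG00000017716, chromosome 11, 117849251 to 117855743), Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), Smoc2 (ENSMUSG00000023886, chromosome 17, 14279506 to 14404790) and Hic1 (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519) are protein-coding genes, and the counts are of 3' ends of their transcripts.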

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

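The tests in this part were chosen only after the results were seen, except those of near-identical copies and of cells that hold 2 cell types. The other sorted classes were outside the main comparisons, and for each class and day the gene of highest ratio to the quiescent library with at least 200 CPM, above its level in the progenitor-like cells of the same library, is given. Mitochondrially encoded, ribosomal protein, haemoglobin and predicted genes were left out of this ranking. So were the 74 genes lower in both the day 2 and day 4 libraries. Among them is Apoe, at 1896 CPM in tenocyte-like cells at day 14 against 455 in the quiescent library. In tenocyte-like cells Mmp3 was at 1952 CPM at day 1 against 0, at least 276-fold higher. Serpina3n was at 279.7 CPM at day 2 against 2.36, 118-fold (20.8 to 4723) higher. Mmp13, a collagenase gene, was at 6555 CPM at day 4 against 0, at least 926-fold higher, and at 39.1 in progenitor-like cells. Cluster 16, which Mmp13 leads, held 49 of the 103 tenocyte-like cells at day 4, 50 of 64 at day 2 and 1 of 109 in the quiescent library, so these pools differ in make-up. Ctsf was at 248 CPM at day 14 against 70.8. In mural-like cells Thbd, thrombomodulin, was at 291 CPM at day 1 against 20.8, Apod at 312 at day 2 against 57.2, Stmn1 at 516 at day 4 against 20.8 and Nrip2 at 415 at day 14 against 109. These classes held 64 to 754 and 34 to 246 cells per library, so their values rest on few cells.

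In progenitor-like cells 74 genes were lower in both the day 2 and day 4 libraries, among them Rps2 at 393.7 and 191.9 CPM against 1754 in the quiescent library and 3508 at day 1. A response of progenitor-like cells alone is argued against for the 33 genes also lower in both other classes. They were 44.6% of the 74, against a bound of 25% set for that. For the other genes it stays open. Among them is Smoc2, at 2362 CPM in quiescent progenitor-like cells, 51.9 in tenocyte-like and 52.0 in mural-like cells. A difference in preparation or read processing between 2 sets of libraries cannot be told apart from the time points. The pair had 33 genes lower in all 3 classes, against at most 3 for any other pair, but of 47 genes higher in both libraries in progenitor-like cells 0 were higher in all 3 classes, against 5 for the quiescent and day 14 pair. Near-identical copies as the whole cause are argued against, because 31.1% of the genes (20.8 to 42.9) had a copy at the 3' end and 25.3% of matched genes did. Of the 33 genes lower in all 3 classes 39.4% (22.9 to 57.9) had a copy, so a part played by copies stays open. A response shared by all 3 classes at days 2 and 4 stays open and was not tested.

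Tenocyte transcripts summed over 9 genes were at 138.5 CPM (131.5 to 145.7) in day 14 progenitor-like cells and 34.4 (30.1 to 39.1) in quiescent ones, with 20180 in tenocyte-like cells at day 14. Free RNA from tenocyte-like cells as the source cannot be told apart, because progenitor-like cells held 0.724 of these UMIs per cell and mural-like cells 0.411, a ratio of 1.76 (1.44 to 2.18) whose interval includes the bound of 1.5. As CPM the mural-like cells at day 14 were at 125.1 (101.9 to 152.0), a ratio of 1.11 (0.904 to 1.37) that lies below 1.5. At day 4 the ratio was 9.01 (4.13 to 24.6) per cell and 5.10 (2.34 to 13.9) as CPM, from 6 UMIs in mural-like cells. Single genes differed at day 14, so the sum does not speak for each. As CPM, Comp was 8.28-fold (2.27 to 68.8) higher in progenitor-like than in mural-like cells, from 2 UMIs in the latter. Fmod was at 0.674 times (0.510 to 0.908) its mural-like level, and the intervals of the other genes included equal levels. Cells that hold both a tenocyte-like and a progenitor-like cell cannot be told apart either, because the 16 cells with 10 or more such transcripts held 35.8% of 1498, between the bounds of 10% and 50%. A tenogenic state of some progenitors at day 14 stays open and was not tested.

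Clusters 1, 2, 6 and 11, which held 1698 of the quiescent progenitor-like cells, also held 162 at day 2 and 1075 at day 4. Leakage of cells or reads from the quiescent or day 14 library is argued against, since 52 genes that part the library sets in tenocyte-like and mural-like cells were at 0.283 times (0.274 to 0.293) their quiescent level in these cells at day 2 and 0.257 times at day 4. Low UMI numbers as the cause cannot be told apart, because these cells were 0.71% of the progenitor-like cells with at least the median UMIs and 13.6% of the others at day 2, a ratio of 0.0520 (0.0220 to 0.105), and 8.61% and 50.4% at day 4, a ratio of 0.171 (0.143 to 0.203) that lies between the bounds of 0.1 and 0.5. Parts of the limb that notexin did not reach could be a source and were not tested.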

How the results depend on the processing

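No paired analysis was possible because each group is 1 library, and all alternatives with doublet scores removed, cells of at least 3647 UMIs, unnamed clusters added or the 33 genes left out were chosen only after the result was seen. Of 1222 values for 112 list medians under alternatives, 1152 kept their position against random lists, 38 lost and 30 gained a position, and 2 reversed, both with all classes, where the day 4 medians were -1.87 for the tenogenic and -0.57 for the mural list. Of 1664 values for 167 ratios of named genes, a gene being counted once per comparison, 1534 stayed within 0.5 log2 units of the reported ratio and 130 moved. Of 228 counts of genes, 179 stayed within 1.5 times. Shares of cells were held to the interval of the reported share, and 53 of 75 values for classes and 21 of 40 for cycle transcripts stayed inside it. TMM gave 1946 genes higher and 726 lower at day 1, 1152 and 695 at day 2, 331 and 801 for day 2 against day 1, and 158 genes highest in the quiescent library, 638 at day 1 and 178 at day 14. DESeq2 factors gave 1977 and 708 at day 1, 1284 and 635 at day 2, 755 lower for day 2 against day 1, and 154 highest in the quiescent library, 650 at day 1 and 171 at day 14. By construction these move all ratios of a library together, and they alter which genes reach a minimum. A minimum of 5 CPM admits more genes and gave 2784 lower at day 1, 2020 lower at day 2, 714 higher and 1087 lower at day 4, 141 and 129 at day 14, 1074 higher for day 2 against day 1, 683 and 368 for day 4 against day 2, 875 and 616 for day 14 against day 4, and 574, 301, 405 and 553 genes highest in the quiescent, day 2, day 4 and day 14 libraries. A minimum of 50 CPM admits fewer and gave 716 lower at day 1, 463 higher and 532 lower at day 2, 236 and 332 at day 4, 21 and 28 at day 14, 277 and 280 for day 2 against day 1, 246 and 135 for day 4 against day 2, 249 and 206 for day 14 against day 4, and 173, 89 and 152 highest in the quiescent, day 2 and day 14 libraries. With all classes 140 genes were higher at day 14 and 25.4% of day 2 cells had G2/M transcripts. At least 3 UMIs of G2/M genes, a stricter rule, gave 0.369% at day 1, 22.6% at day 2 and 6.43% at day 4, and for S phase genes 1.56% in the quiescent library, 25.6% at day 1, 24.4% at day 2, 6.29% at day 4 and 1.95% at day 14. No thinning, which keeps the deeper cells' depth, gave G2/M shares of 4.51%, 48.5% and 13.6% at days 1, 2 and 4. The progenitor-like share with resolution 2.0 was 87.7% for quiescent, 92.5% at day 1, 91.5% at day 2, 75.0% at day 4 and 68.4% at day 14, and with the stricter filter 86.7% for quiescent and 89.9% at day 4, where mural-like shares were 1.67% for quiescent and 5.63% at day 14. With doublets kept it was 89.8% at day 4, and with the highest doublet scores removed 86.6% for quiescent, 81.8% at day 1, 91.3% at day 4 and 67.6% at day 14. Among cells of at least 3647 UMIs it was 88.8%, 93.2%, 90.8% and 63.4% for quiescent, day 1, day 4 and day 14, and the mural-like share 0.444%, 0.569%, 1.44% and 2.78%. For these class shares and for the reversed medians the cause was not tested. Depth limits the quiescent library most, where 3 counts of a gene set the floor in 6775676 UMIs.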

Other observations

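No test was made in this part, and the genes of the sterol pathway and of the other classes were chosen only after the results were seen. Fdps, Hmgcs1 and Cyp51, 3 genes of the mevalonate and sterol pathway, were highest at day 2 among the 5 libraries of progenitor-like cells, and the pathway as a whole was not tallied. Fdps, farnesyl diphosphate synthase, was at 148 CPM in the quiescent library, 217 at day 1, 566 at day 2, 73.1 at day 4 and 143 at day 14. Hmgcs1, which makes the precursor of mevalonate, was at 94.0, 131, 245, 49.7 and 97.2 CPM in the same order, and Cyp51, a sterol demethylase, at 31.3, 82.3, 149, 25.7 and 39.6. In mural-like cells Fdps was at 129.9 CPM in the quiescent library, 750.3 at day 1 and 689.8 at day 2, and Hmgcs1 at 46.8, 366 and 246.

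Tenocyte-like cells at day 1 had less of the cornea and tendon proteoglycan gene Kera, at 138 against 2332 CPM, and of Tnmd, at 857 against 4987, and more of Il1rl1, at 1335 against 0, and of the enkephalin precursor gene Penk, at 795 against 2.36. Most tenocyte-like cells were in cluster 5 in the quiescent and day 14 libraries and in cluster 16 at day 1. Mural-like cells had less Rgs5, a pericyte regulator of G protein signalling, at day 1, at 3427 against 10810 CPM, and more Il6, at 900.3 against 151. At day 14 they had more Acta2, at 5852 against 2375 CPM, and Tagln, at 2640 against 972, while Myh11, smooth muscle myosin, was at 591 against 489, within counting error (1.21-fold, 0.968 to 1.52). The lower limit of UMIs differs between these libraries and mural-like cells are poor in RNA. Progenitor-like cells of clusters 1, 2, 6 and 11 had more Pi16, a marker of adventitial fibroblasts, at day 4, at 7942 against 2404 CPM, more Irf7, at 144 against 25.3, and more Postn, at 468 against 93.0. They had less Smoc2, one of the 74 genes that part the library sets, at 193 against 2404. These pools differ in make-up, since cluster 1, with Pi16 among its leading genes, held 758 of the 1075 cells at day 4 and 333 of 1698 in the quiescent library, and cluster 2, with Smoc2 among its leading genes, 110 and 774. Postn was higher still over the whole progenitor-like class at day 4. Free RNA could thus add to its value in cells of these clusters, which was not tested. Of 15 interferon genes compared in these cells at day 4, 7 were at least 2-fold higher than in the same clusters of the quiescent library and 0 lower.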
